A study of Homo sapiens with 3 samples.

How the data were processed

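Poly(A) RNA sequencing libraries were made from MG-OKS cells, described in the series title as artificially generated osteosarcoma cells resembling cancer stem cells. There were 3 groups with 1 library each, namely untransfected cells, cells given a scrambled siRNA, and cells given an siRNA directed at SPRR1A. Per the labels' protocols, the cells were grown in DMEM with fetal bovine serum, the siRNAs were delivered with a lipid transfection reagent, total RNA was isolated on columns, and stranded mRNA libraries were prepared. The untransfected group was taken from the sample title and both siRNA groups from the genotype labels, and count columns were matched by sample title. The sequence of neither siRNA was given in the sources used here.

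The authors deposited a table of whole-number read counts per gene together with FPKM and TPM values for the same genes and libraries. Per the submitters' processing notes, reads were aligned with HISAT2 version 2.1.0 and the human builds GRCh38 and hg38 were named. The counting tool, the annotation release and whether counting used the strand were not given in the sources used here. Per the file headers, genes carry NCBI Gene identifiers and symbols. The deposited TPM summed to 999225, 999391 and 999131 in the untransfected, scrambled and SPRR1A siRNA libraries, and the deposited FPKM columns were read only to check that they were of the same order in each library. Low counts were even slightly more often than odd, with 51.8%, 51.1% and 51.2% even values among counts of 1 to 20 in the untransfected, scrambled and SPRR1A siRNA libraries. No column of the deposited counts was left unassigned to a library.

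The table held 46427 genes, of which 14233 (30.7%) reached 1 CPM in at least 1 library and were kept. Total counts were 40050593 in the untransfected, 36533542 in the scrambled and 34453554 in the SPRR1A siRNA library. TMM factors from edgeR 4.0.16 in R 4.3.3 were 1.0169, 0.994 and 0.9892 in that order. CPM values, counts relative to the library size scaled by these factors, were computed, and log2 ratios with a prior count of 2. A floor of 3 counts corresponded to 0.0737, 0.0826 and 0.088 CPM per library in that order. Levels carried exact Poisson 95% intervals and ratios carried exact conditional binomial 95% intervals. Reads were not marked by molecular identifiers, so intervals and floors cover counting error only.

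With 1 library per group no difference has a replicate check, no dispersion was estimated and no p-value was computed. A gene was called higher or lower when the log2 ratio was at least 1 in size and the 95% counting interval of the ratio excluded 1. This rule compares libraries, not conditions. The SPRR1A siRNA library was compared with the scrambled library as the main comparison and with the untransfected library as a second comparison, and the controls were compared with each other as a yardstick. Genes called in the same direction against both controls were counted. Since both comparisons share the SPRR1A siRNA library, 100 simulations of 3 unchanged libraries were run with Poisson counts and with biological coefficients of variation (BCV) of 0.1, 0.2 and 0.4, and the overlap of independent lists was computed. In data simulated at a BCV of 0.1 for the SPRR1A siRNA library against both controls, over 13942 genes, the rule recovered 96% of genes set 3-fold higher, 92% of those set 3-fold lower, 100% of those set 5-fold higher and 96% of those set 5-fold lower, and called 0.015% of unchanged genes. At that BCV unchanged libraries gave 6.2 higher and 7.2 lower genes between the controls, against 215 and 490 observed. These rates thus belong to a quieter setting and may not hold for these libraries.

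A total of 29 gene lists was fixed before the data were examined. They covered the SPRR and cornified envelope genes, epithelial and keratinocyte markers, pluripotency factors, cancer stem cell markers, osteoblast, chondrocyte, adipocyte and endothelial or blood cell markers, interferon response, NF-kB and inflammatory cytokines, G1/S and DNA replication, G2/M and mitosis, p53 targets, unfolded protein and integrated stress response, sterol biosynthesis and uptake, hypoxia and glycolysis, fibrillar matrix, matrix proteases and invasion, epithelial-mesenchymal transition (EMT) factors, TGF-beta and YAP targets, Wnt targets, immediate early genes, apoptosis regulators, oxidative stress response, small interfering RNA machinery, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts and replication-dependent histones. For each list the median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. If the lists held randomly drawn genes, about 1.45 of the 29 would do so in each comparison. Genes of the same list may vary together between single cultures, which the random lists do not copy, so more lists may stand apart without any effect of an siRNA. These percentiles describe these libraries. The lists share some members, so they are not independent of each other.

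Genes named in the text followed a rule fixed before the data were examined. It took the kept SPRR genes, POU5F1, SOX2, KLF4 and MYC, the 12 higher and 12 lower protein-coding genes standing farthest from both controls at a mean of 5 CPM or more, the 8 higher and 8 lower genes farthest apart between the controls by the same filters, and up to 4 members of each list with the largest ratio between the SPRR1A siRNA and scrambled libraries. Other genes were named as overlapping partners of these or as SPRR genes at 0, and every further gene was chosen after its values were seen and is marked so. Values of some single genes are not reported here, while the list counts and medians include them. Genes at 0 counts in 1 library of a comparison were given as bounds at the floor of 3 counts per library. The calls included 31, 32 and 15 such genes in the SPRR1A siRNA against scrambled, SPRR1A siRNA against untransfected and scrambled against untransfected comparisons, and all of them stayed at least 2-fold apart at that bound. Among list members 1 gene was at 0, and its list's medians, -0.25 and -0.53, did not move at the bound.

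Gene coordinates and biotypes came from the RefSeq annotation of GRCh38.p14, matched by NCBI Gene identifier for 44698 genes, and transcript sequences from GENCODE release 29. Neither is stated to be the annotation the authors counted with. Short sequence searches used the longest annotated 3' UTR of at least 50 bases per gene, which 12180 kept genes had. For each library-specific gene set every 7-base sequence was scored as a z of the number of genes holding it against the number expected within 10 bins of 3' UTR length and 5 of GC content, and compared with the highest z in 100 random gene sets matched on both. Smooth trends on GC content and length used a lowess fraction of 0.3, and 1000 bootstrap draws over genes gave the intervals of median shifts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

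Alternatives tried were total count scaling, DESeq2 1.42.0 size factors, library sizes without mitochondrial and the 10 most abundant genes, no filter, a filter of 5 CPM, prior counts of 0.5 and 10, a 1.5-fold threshold, size without the counting interval, the deposited TPM as log2(TPM + 1), protein-coding genes alone, and for lists the mean, matching on length and the untransfected comparator. Added after the data were seen were counting intervals from halved counts, leaving out genes holding the enriched 7-base sequences, and removal of GC and length trends.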

Results

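RNA from MG-OKS cells, an osteosarcoma line generated to resemble cancer stem cells and labelled as mesenchymal, was profiled by stranded mRNA sequencing. The design asked what lowering SPRR1A, a small proline-rich protein of the epidermal cornified envelope, does to these cells. An siRNA directed at SPRR1A was compared with a scrambled siRNA and with untransfected cells. Each condition was represented by 1 library, with 34453554 counts in the SPRR1A siRNA, 36533542 in the scrambled and 40050593 in the untransfected library. Counts were found for 21116, 21388 and 22040 genes in that order. No difference reported here has a replicate check, and intervals are 95% counting intervals.

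SPRR1A itself (NCBI Gene 6698, chromosome 1, 152984081 to 152985814 in GRCh38) had 0 counts in the untransfected, the scrambled and the SPRR1A siRNA library. A floor of 3 counts per library corresponds to 0.0737, 0.0826 and 0.088 CPM, respectively. It bounds the level only if reads of SPRR1A were not lost in counting. No fold could be given, so the targeted transcript neither checked nor contradicted the labels. The paralogues SPRR1B and SPRR2G were also at 0 in all 3 libraries. Of the SPRR genes, 3 passed the expression filter. SPRR3 (Gene 6707, chromosome 1, 153001749 to 153003856) had 482 counts in the untransfected, 547 in the scrambled and 129 in the SPRR1A siRNA library, which made it 3.98-fold lower than in the scrambled library (95% interval 3.28 to 4.86) and 3.13-fold lower than in the untransfected library (2.57 to 3.83). Its 3' UTR held GTCACCC, the 7-base sequence found in most of the 12 genes farthest below both controls. SPRR2E had 47, 208 and 17 counts and was 11.5-fold lower than in the scrambled and 2.31-fold lower than in the untransfected library. SPRR2D had 74, 254 and 55 counts and was 4.33-fold lower than in the scrambled library, with a log2 ratio of -0.17 to the untransfected library. The SPRR2 genes are close paralogues whose reads could be split between them, so their values are uncertain.

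Against the scrambled library, the median of the sterol list in the SPRR1A siRNA library lay above matched random lists, and the medians of the osteoblast, fibrillar matrix, interferon and epithelial lists lay below them, while most members of each list were not called. For the osteoblast, matrix and epithelial lists this depended on a setting given with the list. Of 14233 genes, 527 were at least 2-fold higher and 1034 at least 2-fold lower. Against the untransfected library 334 were higher and 1190 lower, and 146 were higher and 661 lower than in both controls. Opposite calls against the controls were found for 10 genes. The median log2 ratio of all kept genes was near 0 in each comparison. Between the controls, 215 genes were higher and 490 lower in the scrambled than in the untransfected library. Independent lists of these sizes would share 12.4 higher and 86.5 lower genes. Simulated unchanged libraries shared on average 0.7 higher and 1.6 lower genes at a BCV of 0.1, 15.6 and 35.6 at 0.2, and 496.9 and 725.2 at 0.4. Between the controls the simulation gave 6.2 higher and 7.2 lower genes at 0.1, 156.0 and 161.8 at 0.2, and 1709.6 and 1708.5 at 0.4. Observed were 215 and 490, more than at 0.2 and fewer than at 0.4. The controls also differ in treatment, so the BCV and the overlap of unchanged libraries were not fixed by this. Part of the excess over independent lists may come from the shared library, which the simulated values include. The counts moved by more than 1.5 times with no filter, with a filter of 5 CPM, with a 1.5-fold threshold and with log2(TPM + 1).

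**Figure D1:**
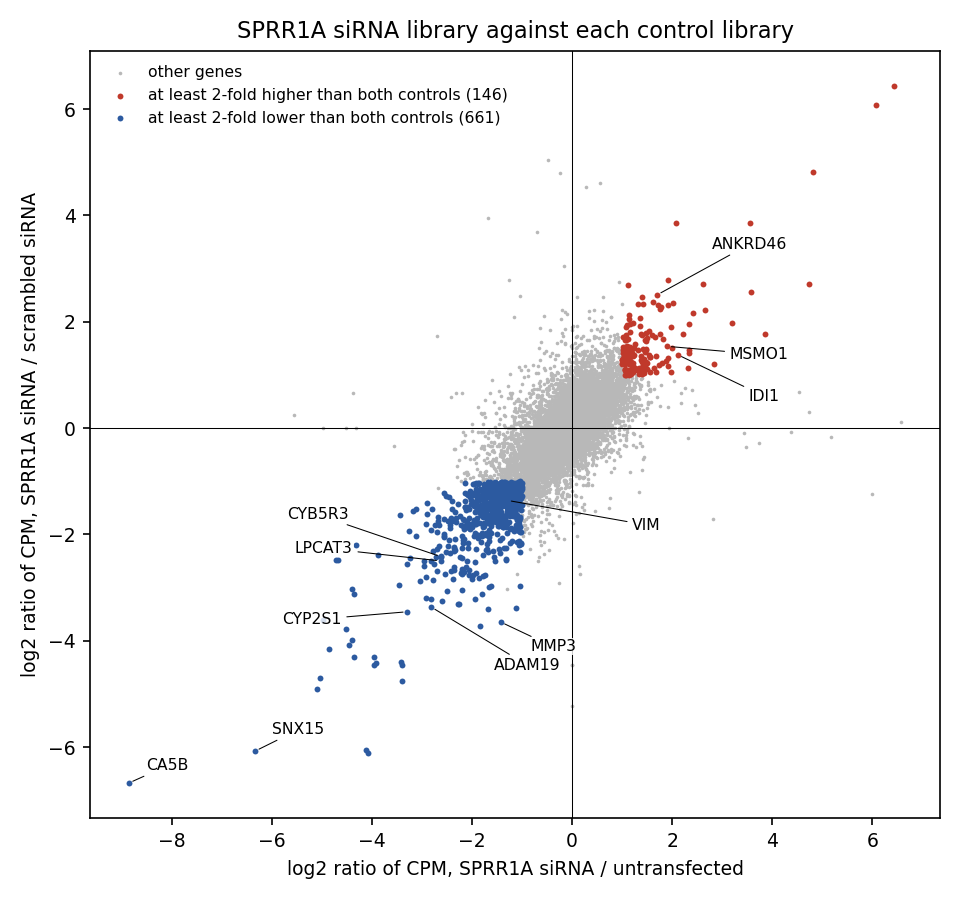
Each point is 1 of 14233 genes, with the log2 ratio of CPM (prior count 2) of the SPRR1A siRNA library to the untransfected library on the x axis and to the scrambled library on the y axis, from 1 library per condition. Red points mark the 146 genes higher and blue points the 661 genes lower than in both controls, and the position of CA5B, at 0 counts in the SPRR1A siRNA library, depends on the prior count.

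Among the genes farthest above both controls, MSMO1, a sterol C4-methyl oxidase (Gene 6307, chromosome 4, 165327669 to 165343164), was 2.91-fold higher than in the scrambled library (2.77 to 3.05) and 3.74-fold higher than in the untransfected library (3.55 to 3.94). IDI1, isopentenyl diphosphate isomerase of the mevalonate pathway, was 2.60-fold and 4.33-fold higher. HSD17B7, which acts in cholesterol synthesis, was 2.65-fold and 5.11-fold higher. STARD4, a sterol transport protein, was 2.61-fold and 2.91-fold higher. Outside sterol metabolism, ANKRD46 was 5.73-fold (4.97 to 6.63) and 3.26-fold higher. The zinc finger gene ZNF699 was 3.47-fold and 2.77-fold higher. CALD1, encoding the actin-binding protein caldesmon, was 2.72-fold and 2.76-fold higher. TLCD2 was 3.45-fold and 2.60-fold higher. The kinase gene SIK1 was 2.83-fold and 2.79-fold higher, and its near-identical copy SIK1B was 2.78-fold higher against each control, so that their reads cannot be assigned with certainty. The readthrough genes HSPE1-MOB4 (5.01-fold and 3.79-fold higher) and RPL36A-HNRNPH2 (3.58-fold and 2.90-fold higher) completed the 12 and are uncertain, because they overlap the genes they join.

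Among the genes farthest below both controls, CYP2S1, a cytochrome P450 (Gene 29785, chromosome 19, 41193219 to 41207539), had 1171 counts in the untransfected, 1163 in the scrambled and 98 in the SPRR1A siRNA library, and was 11.1-fold lower than in the scrambled library (9.06 to 13.8). ADAM19, a membrane metalloproteinase, was 10.4-fold lower than in the scrambled (8.89 to 12.2) and 7.11-fold lower than in the untransfected library. CYB5R3, cytochrome b5 reductase, was 5.35-fold and 6.15-fold lower, from 249.4 CPM in the scrambled to 46.59 CPM in the SPRR1A siRNA library. LPCAT3, a phospholipid acyltransferase, was 5.68-fold and 6.23-fold lower. The collagenase MMP1 was 7.46-fold and 5.42-fold lower. The caveolar gene CAVIN2 was 7.14-fold and 7.84-fold lower, the coronin CORO2B 5.95-fold and 6.86-fold, and the solute carriers SLC12A8 6.90-fold and 5.98-fold and SLC35A4 6.43-fold and 5.38-fold. AP1M1, a subunit of the AP-1 clathrin adaptor, was 6.11-fold and 5.12-fold lower. SNX15 fell from 1204 counts in the scrambled to 15 in the SPRR1A siRNA library, but the overlapping readthrough gene ARL2-SNX15 had 297 and 594 counts, and the sum of both was 2.31-fold lower. CA5B had 1020, 198 and 0 counts in the untransfected, scrambled and SPRR1A siRNA libraries, at least 61.9-fold lower than in the scrambled library, while the overlapping CA5BP1-CA5B had 347, 579 and 419 counts. The sum of those was 1.74-fold lower than in the scrambled library, so both genes are uncertain. Of these 12 genes, 10 held the same 7-base sequence, GTCACCC, in the 3' UTR, which 12.4% of searched genes held. Of the further genes named, SPRR3, ID3, IL11, IRAK2, OAS3, SEPTIN5 and TLCD2 held it as well.

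Sterol biosynthesis and uptake genes stood above as a group. Of 24 kept members, 9 were higher than in the scrambled library and 1 was lower, with a median log2 ratio of 0.66 that lay above all 10000 random lists. Against the untransfected library 15 members were higher and none lower, and the median was 1.17, also above all random lists. All 9 members higher than in the scrambled library were higher than in both controls. Chosen after their values were seen, HMGCS1, the cytosolic HMG-CoA synthase, had log2 ratios of 1.12 and 2.32 to the scrambled and untransfected libraries, the squalene-forming FDFT1 had 1.23 and 1.80, and squalene epoxidase SQLE had 1.26 and 1.88. The scrambled library lay between the others, with a median of 0.49 over the untransfected library that was also above all random lists, although only HMGCS1 reached 2-fold there, at a log2 ratio of 1.20. The ordering from SPRR1A siRNA over scrambled to untransfected was found in 19 of the 24 members and in 19.8% of all kept genes.

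**Figure D2:**
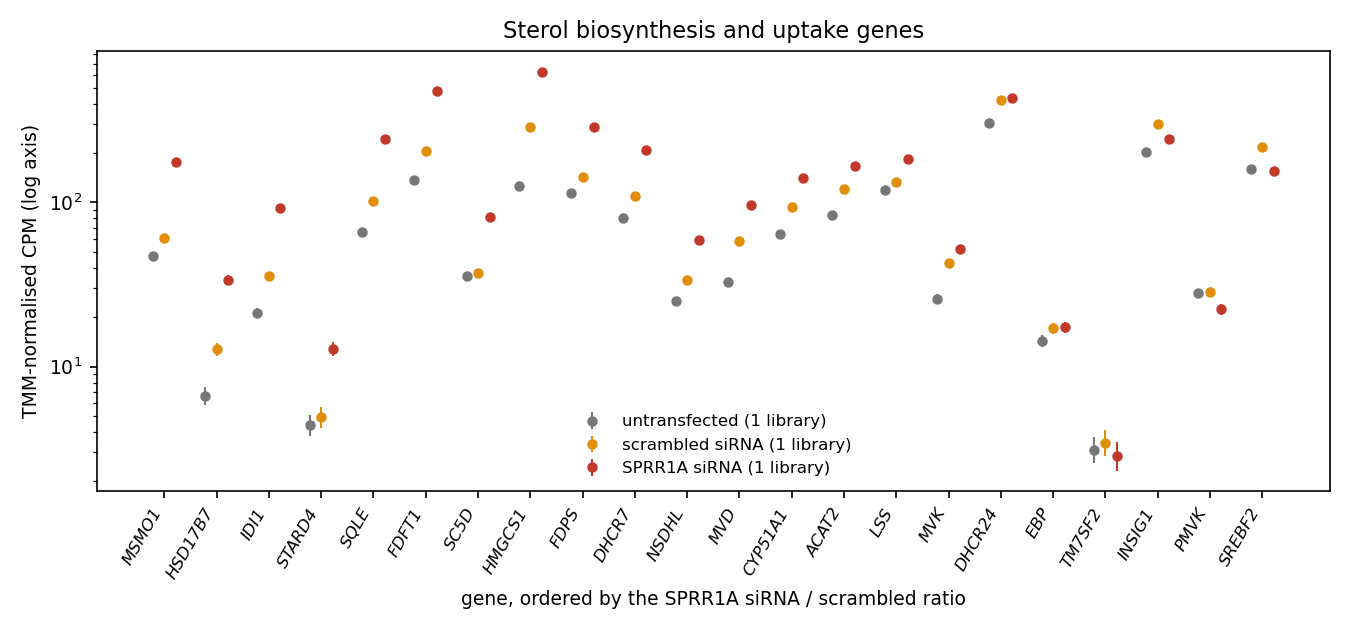
TMM-normalised CPM on a log axis of 22 of the 24 sterol biosynthesis and uptake genes kept, in the untransfected (grey), scrambled (orange) and SPRR1A siRNA (red) libraries, 1 library each, with bars for the exact Poisson 95% interval. In 18 of the 22 genes drawn the SPRR1A siRNA library was highest and the untransfected library lowest.

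Osteoblast genes stood below as a group. Of 14 kept members, 4 were lower than in the scrambled library and none higher, with a median log2 ratio of -0.88, below all random lists, and a median of -0.61 (percentile 0.12) to the untransfected library. TNFRSF11B, the decoy receptor osteoprotegerin, was 4.07-fold and 4.61-fold lower than in the scrambled and untransfected libraries. The vitamin D receptor gene VDR was 3.07-fold and 3.60-fold lower, and the homeobox gene MSX2 was 2.12-fold and 2.33-fold lower. The fourth was SPP1, osteopontin, chosen after its values were seen, with 28 counts in the untransfected, 86 in the scrambled and 6 in the SPRR1A siRNA library. RUNX2, the osteoblast transcription factor, chosen after its values were seen, went the other way without being called, with log2 ratios of 0.70 to the scrambled and -0.34 to the untransfected library. COL1A1 was 3.26-fold lower than in the untransfected library and 1.97-fold lower than in the scrambled library, where it did not meet the rule. Without the expression filter the median of the list was -0.22 and no longer stood apart.

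Fibrillar matrix genes had 6 lower and 1 higher of 28 members against the scrambled library, with a median of -0.25 (percentile 0.56), and 10 lower and none higher against the untransfected library, with a median of -0.53. The median did not stand apart with a filter of 5 CPM (-0.15). LUM, encoding the proteoglycan lumican, was 3.15-fold lower, COL3A1 2.67-fold, COL5A2 2.39-fold and tenascin C (TNC) 2.19-fold lower than in the scrambled library. The higher member was the crosslinking enzyme gene LOX, at 2.06-fold, but at only 1.08-fold to the untransfected library. The scrambled library was itself below the untransfected library on this list, with a median of -0.22. EMT factors had a median of -0.26 (percentile 1.65) to the scrambled library, with 2 lower and 1 higher of 18 members. VIM, the intermediate filament vimentin, was 2.56-fold lower (2.54 to 2.59), ITGA5, a fibronectin receptor subunit, 2.97-fold lower, and the ligand gene WNT5B 2.78-fold higher. This call was lost when random lists were matched on length. Against the untransfected library the median was -0.58, below all random lists. Matrix proteases had 5 lower and 1 higher of 22 members, with a median of -0.22 (percentile 2.94) that did not stand apart against the scrambled library but did against the untransfected library (-0.48). MMP3 was 13.1-fold lower than in the scrambled library but 2.77-fold lower than in the untransfected library (116, 490 and 35 counts in the untransfected, scrambled and SPRR1A siRNA libraries), MMP2 2.29-fold and the urokinase gene PLAU 2.13-fold lower than in the scrambled library. The remaining members called, TIMP2 (-1.02) and CTSK (1.11), were chosen after their values were seen.

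Interferon response genes had 8 lower and none higher of 20 members, with a median of -0.59 (percentile 0.05) to the scrambled library, and 3 lower with a median of -0.46 (percentile 1.76) to the untransfected library. The oligoadenylate synthetase genes OAS1 and OAS3 were 5.35-fold and 2.65-fold lower than in the scrambled library, IFI44 was 4.55-fold lower and DDX60 2.29-fold lower. OAS1, OAS3 and IFI44 were lower than in both controls. NF-kB and cytokine genes had a median of -0.40 (percentile 0.93) to the scrambled library, with IRAK2 4.57-fold lower, but 0.13 (percentile 86.09) to the untransfected library, and the mean did not stand apart. Besides IRAK2, IL1A (-1.31) was lower and IL11 (1.12) higher than in the scrambled library, both chosen after their values were seen.

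Epithelial and keratinocyte markers had 5 lower and none higher of 19 members, with a median of -0.36 (percentile 0.61) to the scrambled library and -0.90 (below all random lists) to the untransfected library. The call against the scrambled library was lost with a filter of 5 CPM, with library sizes without the most abundant genes and with GC and length trends removed. PERP, a desmosomal protein gene, was 3.74-fold lower, SFN (14-3-3 sigma) 2.32-fold and the hemidesmosomal integrin ITGB4 2.29-fold lower than in the scrambled library. TP63 (-1.68) and CLDN1 (-1.40), chosen after their values were seen, were also lower. The abundant keratins KRT6A (0.53) and KRT14 (0.41), besides KRT5 (0.96) and DSP (0.70), had ratios above 0 to the scrambled library and below 0 to the untransfected library without being called, and were also chosen after their values were seen. The SPRR and cornified envelope list had 3 lower and none higher of 9 members, the SPRR genes above, with a median of -0.95 (percentile 0.27), and -1.03 to the untransfected library. Only SPRR3 of this list held GTCACCC or the sequence of the scrambled library given below. Without that gene the median was -0.47 and did not stand apart.

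The reprogramming factor genes did not meet the rule against the scrambled library. POU5F1 had log2 ratios of -0.52 to the scrambled and -0.96 to the untransfected library, KLF4 had -0.72 and -0.97, and MYC had -0.24 and 0.13. SOX2 had -0.63 to the scrambled library and was 2.16-fold lower than in the untransfected library (2.06 to 2.28). The series title calls these cells artificially generated. If copies of these genes were introduced, counts per gene cannot tell their transcripts from those of the cells' own genes. The pluripotency list had 1 lower of 9 members, KLF2 at 2.06-fold. The list's median to the scrambled library was -0.52 (percentile 0.94), which is the value of POU5F1. To the untransfected library it was -0.25 (percentile 11.37). Against the scrambled library the list no longer stood apart with the mean or with GC and length trends removed. Cancer stem cell markers had 1 higher and 2 lower of 16 members, with a median of -0.16 (percentile 7.89). The adhesion molecule gene ALCAM was 4.64-fold higher than in the scrambled library, in which it was 3.45-fold lower than in the untransfected library. The drug efflux transporter ABCG2 was 5.68-fold and 2.54-fold lower than in the scrambled and untransfected libraries. ALDH1A1 (-1.94), chosen after its values were seen, was lower than in the scrambled library. Against the untransfected library this list stood below, with a median of -0.50 (percentile 0.03).

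G1/S and DNA replication genes stood below in small steps, with a median of -0.31 (percentile 0.02) and 1 lower of 32 members, the replication factor GINS3 at 2.25-fold. The median to the untransfected library was -0.32. G2/M and mitosis genes had a median of 0.01 (percentile 33.49), with the mitotic activator CDC20 2.73-fold lower, and -0.09 (percentile 1.06) to the untransfected library, where CDC20 was 2.37-fold lower and the list no longer stood apart with matching on length or by the mean. Adipocyte markers had a median of -0.49 (percentile 0.66), with the lipid droplet gene PLIN2 2.22-fold lower, but -0.08 to the untransfected library, and did not stand apart by the mean. Oxidative stress genes had a median of -0.20 (percentile 2.28), with 1 lower member, AKR1B10 (-2.91, chosen after its values were seen), but 0.19 to the untransfected library. That call was lost by the mean, with matching on length and with GC and length trends removed. Replication-dependent histones had a median of 0.72 to the scrambled library (percentile 99.99) and of 0.72 to the untransfected library (above all random lists), with no member called against the scrambled library. Histone genes are close paralogues, and mRNAs of replication-dependent histones mostly lack the poly(A) tail that these libraries selected for. Their values are therefore uncertain. Genes of the small interfering RNA machinery had a median of 0.37 (percentile 99.74), with TNRC6A 2.63-fold and AGO4 2.14-fold higher and TLR3 (-1.40, chosen after its values were seen) lower, and 0.11 to the untransfected library. Hypoxia and glycolysis genes had a median of 0.20 (percentile 97.52) that barely stood apart and was lost under several alternatives, with LOX and the collagen prolyl hydroxylase P4HA1 higher, the latter at the 2-fold threshold. In all, 4 lists stood above and 11 below against the scrambled library, and 4 and 10 against the untransfected library. Between the controls 7 stood above and 8 below, so lists stood apart about as often without an siRNA directed at SPRR1A.

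The remaining lists did not stand apart against the scrambled library. Medians were -0.10 for p53 targets (1 higher of 24 members), 0.07 for the unfolded protein and integrated stress response (0 of 29 called), 0.13 for TGF-beta and YAP targets (2 higher, 1 lower of 24), -0.17 for Wnt targets (1 higher, 2 lower of 13), 0.13 for apoptosis regulators (1 higher of 29) and 0.01 for immediate early genes (4 lower of 29). Chondrocyte markers had a median of -0.79 (percentile 2.66, 1 lower of 5), and endothelial and blood cell markers -0.19 (percentile 26.1), with none of 8 called in any comparison. Cytosolic ribosomal protein genes (-0.00), nuclear-encoded oxidative phosphorylation genes (-0.06) and mitochondrially encoded transcripts (0.17) had no member called. Against the untransfected library the unfolded protein and integrated stress response stood above (0.36, percentile 99.99), with 1 of 29 members called, SLC7A11 (1.10), chosen after its values were seen. The p53 targets stood above there as well (0.22, percentile 98.06), although only TP53INP1 (3.21) was called higher while DDB2 (-1.24) and PHLDA3 (-1.07) were lower, TP53INP1 and DDB2 being chosen after their values were seen. That call was lost with a filter of 5 CPM, without the genes holding an enriched 7-base sequence, with GC and length trends removed and by the mean. The others of these lists did not stand apart there. TCF7, a Wnt-responsive transcription factor gene, was 2.68-fold lower, DKK1 2.02-fold lower, ID3 2.58-fold lower, PMEPA1 2.63-fold higher and the pro-apoptotic BCL2L11 2.03-fold higher than in the scrambled library. Chosen after their values were seen, the p53 target TP53INP1 (1.98), the Wnt target APCDD1 (1.40) and TAGLN (1.35) were higher. The immediate early genes EGR1 (-2.22) and NR4A2 (-1.61), besides JUND (2.32-fold) and KLF2, and the cartilage collagen COL9A3 (-1.45) were lower, with EGR1, NR4A2 and COL9A3 chosen after their values were seen. Of the list members named as apart from the scrambled library, ALCAM, AGO4, APCDD1, IL11, PMEPA1, TAGLN, AKR1B10, ALDH1A1, IL1A, KLF2, NR4A2 and SPRR2D were not called against the untransfected library, and the scrambled library itself was apart from the untransfected library in the opposite direction. For ABCG2, IRAK2, MMP3, SPP1 and SPRR2E, lower than both controls, the scrambled library was also higher than the untransfected library. Further members not called against the untransfected library, nor between the controls, included COL5A2 (-0.597), PLAU (-0.704), PLIN2 (-0.707), ID3 (-0.73) and JUND (-0.608). DKK1 (-0.855), DDX60 (-0.993), TNRC6A (0.99), BCL2L11 (0.798) and LOX (0.115) were others, all as log2 ratios to the untransfected library. IDI1, LPCAT3, ITGB4, LOX and TCF7 overlap neighbouring genes in the annotation, and reads of such pairs cannot be told apart if counting ignored the strand.

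**Figure D3:**
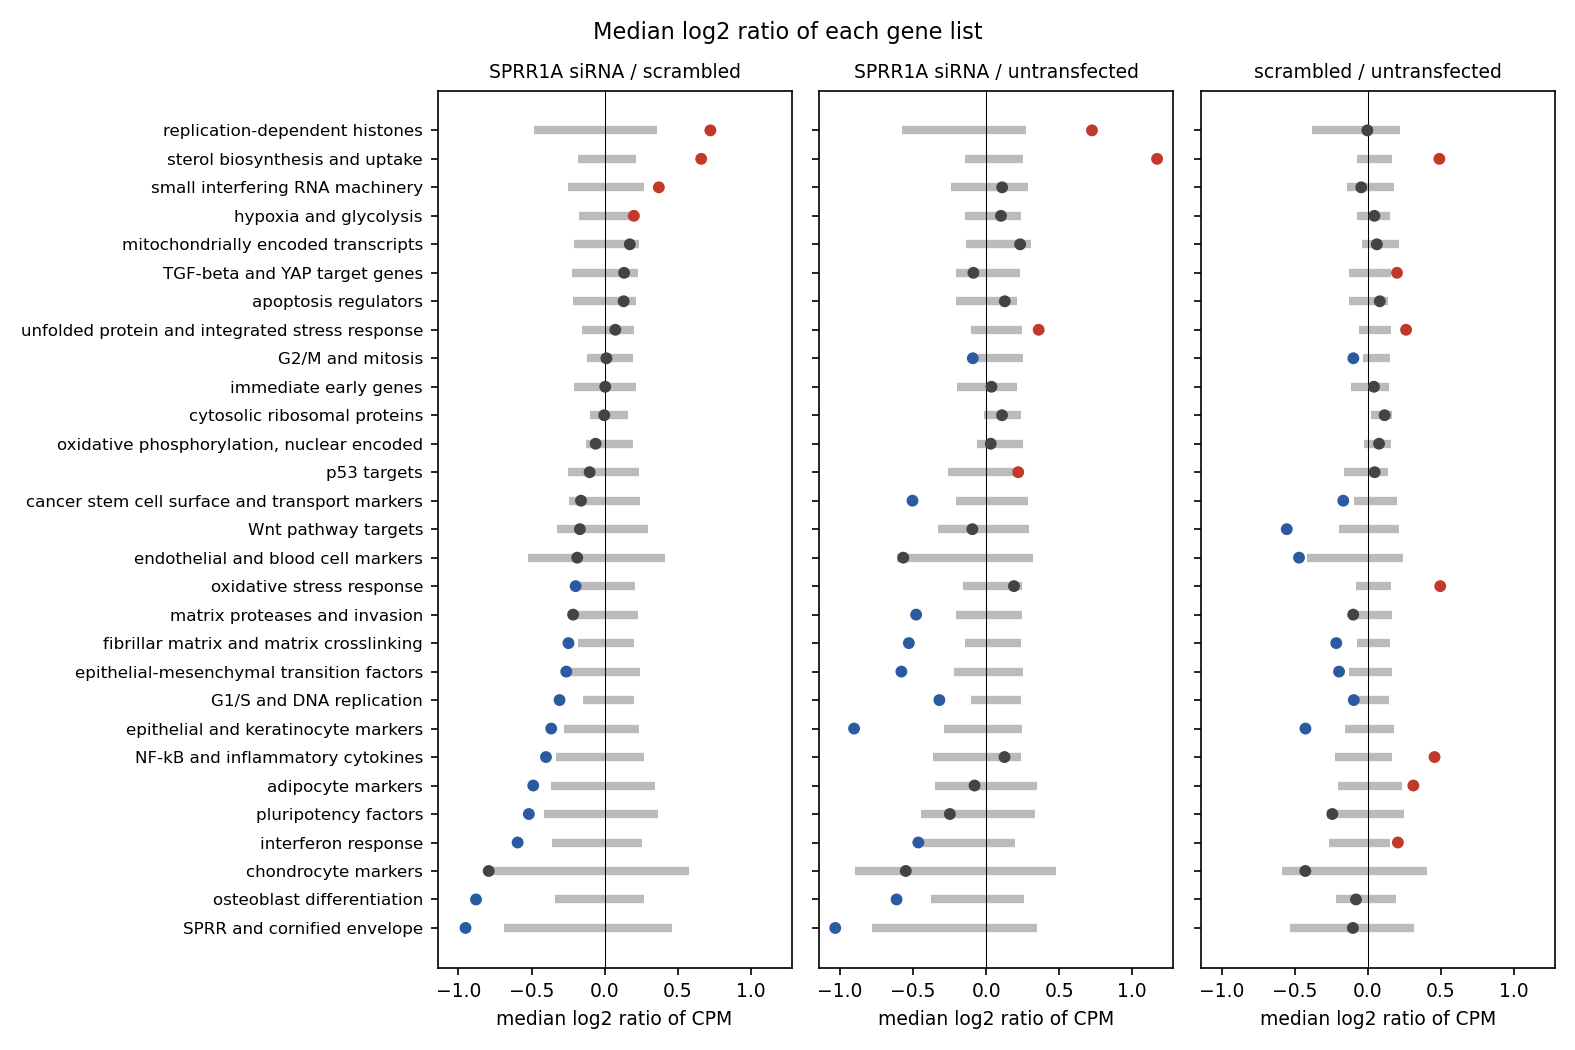
Median log2 ratio of CPM of each of 29 gene lists (points) in the comparisons of the SPRR1A siRNA with the scrambled library, of the SPRR1A siRNA with the untransfected library and of the scrambled with the untransfected library, with grey bars over the central 95% of 10000 matched random lists. Red points lie above and blue points below that range, and the sterol list lies at 0.66, 1.17 and 0.49.

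The comparison of the controls showed what scrambled siRNA transfection and library differences gave together. In the scrambled library the stromelysin gene MMP3 was 4.74-fold higher than in the untransfected library (3.86 to 5.85), the aldo-keto reductase AKR1C1 4.08-fold higher, DDAH1 3.98-fold, the glucosylceramide synthase UGCG 3.11-fold, the apoptosis inhibitor BIRC3 3.10-fold and GXYLT1 2.84-fold higher. The membrane protein gene EMP2 was 6.47-fold lower (5.92 to 7.08), NKAIN1 5.08-fold, SEPTIN5 4.92-fold, CA5B 4.59-fold, NEURL1B 4.57-fold and the basement membrane gene NID1 4.32-fold lower. Readthrough genes made up the rest and are uncertain, with COMMD3-BMI1 17.7-fold and ANKHD1-EIF4EBP3 3.93-fold higher and TPTEP2-CSNK1E 60.4-fold and ATP5MF-PTCD1 9.69-fold lower. Of these 8 lower genes, EMP2, NKAIN1 and NID1 held the 7-base sequence GCAGTAC in the 3' UTR, which 5.3% of searched genes held. RUNX2, ALCAM, AGO4, MSMO1, ANKRD46, MSX2, DSP and TGFB2, named elsewhere, held it too. AKR1C1 has close paralogues and SEPTIN5 overlaps a readthrough gene, so both are uncertain as well. Lists that stood above were oxidative stress (median 0.50, 4 higher of 25), sterol biosynthesis, NF-kB and cytokines (0.46, 4 higher and 1 lower of 18), adipocyte markers (0.31), the unfolded protein and integrated stress response (0.26), interferon response (0.21, none called) and TGF-beta and YAP targets (0.20). The last had 1 higher and 5 lower of 24 members and a mean of -0.04, so median and mean differed in sign. Chosen after their values were seen, members called were AKR1C2 (2.93-fold higher), SLC7A11 (1.16) and AKR1B10 (2.64) besides AKR1C1, and CXCL2 (2.20) and IL1A (2.07) higher and IL11 (-1.32) lower besides BIRC3 and IRAK2 (2.21-fold higher). Of the TGF-beta and YAP targets CCN1 (1.34) was higher, and TAGLN (-1.79), TGFB1 (-1.09), TGFB2 (-1.33), TGFBR1 (-1.04) and PMEPA1 (-1.12) were lower, all but PMEPA1 chosen after their values were seen. Lists below were Wnt targets (-0.55), endothelial and blood cell markers (-0.47), epithelial and keratinocyte markers (-0.43, 6 lower of 19), fibrillar matrix, EMT factors (-0.20), cancer stem cell markers (-0.17), G2/M and mitosis (-0.10) and G1/S (-0.10), and 7 lists stood above and 8 below in all. Since 705 genes were 2-fold apart between the controls, differences of that size arose without an siRNA directed at SPRR1A.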

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

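All alternatives were fixed before the data were examined except counting intervals from halved counts, leaving out genes holding an enriched 7-base sequence, and removing GC and length trends. SPRR1A stayed at 0 in every library, also in the deposited TPM, so no setting gave its ratio a value. Of the 8 gene counts, none moved by 1.5 times or more under either other normalization, the trimmed library sizes, the other prior counts, size alone, protein-coding genes alone, halved counts or without the genes holding a site. Under the scaling alternatives the lower share of genes apart from both controls ranged from 81.9% to 84.0%, against 81.9% in the main analysis. The sterol list stood above in each comparison under every alternative, with medians of 0.595 to 0.733 for the SPRR1A siRNA against the scrambled library, a mean of 0.559, and a median of 1.171 with the untransfected library as the comparator. No called ratio of a named gene changed direction. Of the alternative ratios of named genes, 183 moved past the bounds set by the counting interval and 3345 did not. At these depths a level of SPRR1A under the floor of 3 counts was not detectable. Size alone, without the counting interval, gave 664 genes lower than both controls against 661.

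Gene counts are given as higher and lower for the SPRR1A siRNA against scrambled, SPRR1A siRNA against untransfected, scrambled against untransfected, and both controls. Without the filter they were 1182 and 1964, 958 and 2085, 870 and 1324, and 404 and 1055. With a filter of 5 CPM they were 304 and 576, 174 and 651, 82 and 235, and 73 and 381. These changes follow in part from the number of genes tested. With a 1.5-fold threshold they were 1610 and 2252, 1254 and 2581, 723 and 1386, and 687 and 1561, as a smaller threshold requires. With log2(TPM + 1) they were 289 and 523, 162 and 678, 70 and 228, and 69 and 313, and the cause was not tested.

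List medians of the SPRR1A siRNA against the scrambled library that no longer stood apart follow, and the cause was not tested. Without genes holding a site they were -0.466 for SPRR and cornified envelope and 0.201 for hypoxia. With trimmed library sizes they were -0.267 for epithelial markers and 0.193 for hypoxia, and with log2(TPM + 1) 0.196 for hypoxia. With a filter of 5 CPM they were -0.108 for epithelial markers and -0.151 for fibrillar matrix, and without the filter -0.217 for osteoblast genes. After removing GC and length trends they were -0.249 for epithelial markers, -0.338 for pluripotency, 0.178 for hypoxia and -0.161 for oxidative stress. With random lists matched on length, 0.201 for hypoxia, -0.262 for EMT factors and -0.198 for oxidative stress fell within the random range. The means were -0.311 for pluripotency, -0.413 for adipocyte markers, -0.402 for NF-kB, 0.113 for hypoxia and -0.237 for oxidative stress. Against the untransfected library the medians were -0.248 for pluripotency, -0.079 for adipocyte markers, 0.102 for hypoxia and 0.110 for siRNA machinery, and they changed sign for NF-kB (0.126) and oxidative stress (0.191). Between the controls, the mean of TGF-beta and YAP targets changed sign to -0.042, and 4 lists stood below with matching on length and 5 with the mean, against 8 in the main analysis.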

Other observations

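Tests chosen after the results they measure had been seen were the SPRR1A counts in the controls, the transfection and LXR tests of the sterol list (with and without the genes that prompted the latter), the classes of sites by position, by following base and by longer repeat, and the counts of named genes holding a site. The other tests were set out after the gene counts and list medians had been seen.

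Keratin genes typical of basal and activated keratinocytes were among the abundant transcripts of these cells, which the labels call mesenchymal. Every keratin named here and RUNX2 were chosen after their values were seen. KRT6A had 118668 counts in the untransfected, 47603 in the scrambled and 64499 in the SPRR1A siRNA library, KRT14 had 112208, 40129 and 50186, and KRT16 had 22653, 8530 and 7661. The log2 ratios of the scrambled to the untransfected library were -1.15, -1.32 and -1.24. Keratin genes have close paralogues, so the values per gene are uncertain. KRT5 (-1.92) was lower as well. Keratins of simple epithelia differed, with ratios of 0.14 for KRT8 and -0.20 for KRT18 but -1.14 for KRT19 in the same comparison. RUNX2, the osteoblast transcription factor, was lower in the scrambled library than in the untransfected library (-1.04), with 865, 374 and 571 counts in the untransfected, scrambled and SPRR1A siRNA libraries. Counted over all kept genes, 110 were higher and 154 lower in the scrambled library than in both others, and 212 were higher and 61 lower in the untransfected library than in both others.

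SPRR1A, the target of the siRNA, had 0 counts in all 3 libraries. Lowering of the transcript by the siRNA cannot be the reason, because the higher of the control libraries' SPRR1A counts was 0. Loss of reads shared with near-identical sequences was tested by the share of 50-base windows of the annotated transcript found in no other gene, which was 88.7% (196 of 221), between the bounds of 50% and 90% set for that test. Discarding of shared reads would spare those of the 196 windows found in no other gene's annotated transcripts. As far as exact matches in annotated transcripts go, it would thus not alone bring a level well above the floor to 0, but it may add to another cause. Near matches and copies outside the annotated transcripts were not searched, so the test did not decide. A gene model too short for the mRNA (270 bases without UTRs in GENCODE 29, while the one used by the authors is unknown) and a level under the floor of 3 counts stay open and cannot be told apart here. Whether SPRR1A was lowered in these cells was not measurable.

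Genes lower in 1 siRNA library than in both others carried a 7-base sequence in their 3' UTRs, a different one for each siRNA. GTCACCC was found in 162 of 568 searched genes lower in the SPRR1A siRNA library, against 79.6 expected (z 10.76, highest of 100 random sets 5.77), and GCAGTAC in 52 of 121 genes lower in the scrambled library, against 8.1 expected (z 16.47, highest random 5.27), while no sequence passed the random sets in the other 4 library-specific sets. Seed-mediated off-target repression by each siRNA would give this pattern, a hypothesis that the siRNA sequences would decide. The excess came to 14.5% and 36.3% of the searched genes, so that these exact 7-base sequences in 3' UTRs did not account for most. Other kinds of sites were not counted, so the part owed to all 3' UTR sites is not known. In the genes lower in the scrambled library, the overlapping CAGTACA (z 6.97) and TGCAGTA (z 6.66) also passed the random sets. In those lower in the SPRR1A siRNA library, TCACCCA (z 5.7) stayed just under 5.77. The shares also leave out coding sequence. Genes with a site there only were shifted too, against matched genes without one. The shift was -0.133 (-0.169 to -0.106) for 1036 genes with GTCACCC, SPRR1A siRNA against scrambled. It was -0.188 (-0.211 to -0.161) for 1386 genes with GCAGTAC, scrambled against untransfected. Smaller shifts were found in comparisons without the siRNA concerned. They were -0.029 (-0.056 to -0.004) for GTCACCC, scrambled against untransfected, and -0.043 (-0.081 to -0.011) for GCAGTAC, SPRR1A siRNA against untransfected. An effect of lowering SPRR1A stays open and untested. A following A, usually linked to stronger repression, went with a larger shift for GCAGTAC (-0.387 with it and -0.22 without it, scrambled against untransfected) but not for GTCACCC (-0.171 and -0.285, SPRR1A siRNA against scrambled), where the shifts outside the repeat GTCACCCAGGCTGG were -0.214 and -0.24. Trends on GC content (84.8% of the genes stayed 2-fold lower after its removal, among the 86.8% with a value) and length (95.5%) did not account for the set, and whether the guide was directed at SPRR1A cannot be told apart, since 0 of 1 enriched sequences lay in the annotated SPRR1A transcript, which lacks UTRs.

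The sterol list stood above in the SPRR1A siRNA library against each control. GC content and length trends were argued against as the whole cause, since the median lay at percentile 100 against the scrambled library after their removal, but transfection cannot be told apart, since the percentile of 100 against the scrambled library is the pattern itself and single cultures may differ in how strongly they were transfected, so that this percentile could not have excluded it as first set out. A candidate explanation is a lower sterol signal: 11 kept targets of the sterol-sensing receptor LXR had a median of -0.549 against the scrambled library (percentile 0.49). ABCA1 was 3.37-fold lower but SCD (0.18), APOE (0.12) and PLTP (0.08) were not lower, these 4 chosen after their values were seen. LPCAT3 holds GTCACCC, so that its drop is no clear support. Its sum with the overlapping EMG1 was 1.28-fold lower. That sum does not bear on the drop, since EMG1 had far more counts (4761 in the scrambled and 4321 in the SPRR1A siRNA library). ABCA1 and LPCAT3 had been seen to be lower before the list was written, and the 9 others had a median of -0.485 (percentile 1.27) with none called. That median is the value of a member that also holds GTCACCC. The 9 targets without that sequence, ABCA1 among them, had a median of -0.549 (percentile 0.92). For all 11 targets the percentile was 4.3 against the untransfected library. Between the controls, where the sterol list also stood above, it was 68.9 (median 0.056). Lowering of SPRR1A, an off-target effect of the siRNA and differences between single cultures all stay open and were not tested.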
